A study of Mus musculus with 8 samples.

How the data were processed

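Total RNA from 8 samples of mouse ES cells, 2 in each of 4 groups, was extracted with Trizol and column clean-up, amplified into biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The authors deposited a table of probe intensity values that were not normalized between arrays, and, per the file headers, each intensity comes with a detection p-value, the authors' measure of whether a probe exceeds background. No intensity was below 52.07 units, so no background had been subtracted as far as the values show. The authors also deposited a log2 table of fewer probes. Tested against the intensities, it held exactly the probes with a detection p-value under 0.05 on 4 or more arrays. Every array in it had a median of 9.55, as after a normalization between arrays. Its values correlated with log2 of the same array's intensity at 0.9999 or more. The scanner software and the tool behind the normalization are not given in the sources used here. Columns were assigned to samples by the pairing in the file header, and 0 columns of sample values were left unassigned.

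The groups and the replicate numbers were taken from the sample titles. Intensities were background corrected, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), with control values inferred from the detection p-values and an offset of 16. Probes with a detection p-value under 0.05 on both arrays of at least 1 group were kept, which left 12932. A linear model of the 4 group means was fitted to all 8 arrays with lmFit and eBayes (4 residual and 2.81 prior degrees of freedom), and 6 contrasts were tested. Adjusted p-values are Benjamini-Hochberg adjusted per contrast over the probes tested, with a threshold of 0.05, and come from limma. The printed SE is that of the moderated fit. Sharing the spread was chosen for its degrees of freedom. Among 100 simulations of unchanged groups with the normal group's spread moderated, the comparisons with normal ES cells called 0.4 to 0.59 probes on average and the others 0. With each probe's own unmoderated spread in the normal group they called 173.7 to 176 probes, and the moderated form was chosen after that result was seen.

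Probe names came from the platform annotation given with the files, which named 11960 probes with 1 gene symbol each, none with several, and left 13737 unnamed here. Of the named probes 11953 matched the RefSeq gene table (assembly GRCm38.p6) by gene identifier, which gave chromosomes and gene order. The array files name no genome build, so no coordinates are printed. Of the tested probes 997 had no name. They stay in the counts. For gene lists, chromosomes and named genes, each of 8733 genes was represented by its probe with the highest mean over all arrays. A probe with no detection p-value under 0.05 in a group has only a bound there. Its fold is then given as "at least", the bright group's mean set against the dim group's mean of, per array, the higher of the probe's value and the lowest normalized value among detected probes, with the adjusted p of the fit.

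Before the data were examined, the contrasts, the 23 gene lists, the rule for named genes and the alternatives were fixed. The lists covered imprinted genes, markers of ES cell states, of embryonic lineages and of feeder fibroblasts, and signalling and stress pathways. Named genes were Igf2 and H19, the 8 largest rises and 8 largest falls (4 and 4 in the last 3 comparisons) among genes past the threshold whose groups did not overlap, passing over clone and model names, up to 8 members past the threshold of each imprinted list and up to 4 of other lists. Members that did not pass are given as values, at most 3 per list chosen by level, and a few others named from a count adjusted over the list alone were chosen after their values were seen. Lists with at least 3 measured genes (22 of 23) and chromosomes with at least 10 were tested with camera at a preset correlation of 0.01. No gene list kept its call with an estimated correlation in any comparison, and chromosome 6 did in all 4 where it passed.

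The limma step was checked on simulated data with 200 changed probes among 12932, with the shared spread in every group. For the H19-labelled arrays against parthenogenetic ES cells it recovered 4.4% of changes of 0.5, 74.6% of changes of 1 and 99% of changes of 2 on the log2 scale, with 5.2% false calls. A shift of 1 given to the germ cell list was found by camera in 10 of 10 repeats. The simulated genes varied independently, so this does not test lists whose members move together.

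The alternatives were other background corrections (none, or normexp with an offset of 50), other detection filters, the authors' log2 table, fits of only the groups compared, a trended and robust prior, the replicate number as a block, array weights, and leaving out each array in turn, where a lone array was assumed to vary like the other groups. Added after the data were seen were a fit without both normal arrays and one with each array's fibroblast marker mean as a covariate. Slide as a block was not run because the files name no slide. With 2 arrays a group, no test for outlying arrays or for other splits of the arrays was made.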

Results

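Gene expression was measured with Illumina bead arrays in 4 groups of mouse embryonic stem (ES) cells of a B6D2F1 hybrid background. Normal ES cells carry a maternal and a paternal genome, whereas parthenogenetic ES cells derive from activated oocytes and carry only maternal genomes. The other groups were parthenogenetic ES cells labelled as overexpressing Igf2, a growth factor gene usually expressed from the paternal allele, and parthenogenetic ES cells labelled as having reduced H19, a maternally expressed noncoding RNA gene beside Igf2. Each group had 2 arrays, 8 in all, and this number limits the precision of every comparison. The labels speak of biological replicates without saying that they were separate cultures, so the p-values measure the spread between these arrays. The median intensity per array lay between 172.1 and 197 units, and 47.1% to 49.5% of the probes were detected.

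The replicate arrays of parthenogenetic ES cells and of each modified line correlated across probes at 0.995 to 0.996, and 20 or 21 probes in each pair differed by more than 1 on the log2 scale. The normal arrays correlated at 0.961, and 1027 probes differed by more than 1. Markers of fibroblasts, often used as feeder cells for ES cultures, averaged 11.89 on normal replicate 1 and 10.43 on normal replicate 2 on the log2 scale. The same mean was 11.79 and 11.81 in parthenogenetic ES cells, 11.60 and 11.62 on the Igf2-labelled arrays, and 11.07 and 11.08 on the H19-labelled arrays. All 4 groups shared 1 estimate of each probe's spread, so the gap between the normal arrays widened the error of comparisons without them. In comparisons with normal ES cells it was averaged with the closer pairs, which understates their error. Fits of the groups compared alone have fewer degrees of freedom. They called 0, 2 and 0 probes for parthenogenetic, Igf2-labelled and H19-labelled against normal, where the shared fit called 14, 136 and 650. For H19-labelled against parthenogenetic they called 4039, against 563.

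The targeted gene Igf2 was not higher on the arrays labelled as overexpressing it. Its log2 intensity was 15.55 ± 0.08 there and 15.60 ± 0.03 in parthenogenetic ES cells (SD, 2 arrays each), a change of -0.05 (SE 0.55, adjusted p = 0.992). It was 14.96 ± 0.03 on the H19-labelled arrays, a change of -0.64 against parthenogenetic ES cells (adjusted p = 0.532). Without normal replicate 1 or normal replicate 2, the adjusted p of the latter was 0.00184. On the normal arrays Igf2 stood at 15.62 and 13.63. Its intensity ran from 13183 to 54664 units over the arrays, and the brightest probe of an array reached 64070 to 67905 units, so the upper end of the scale limits what the probe can show of a rise. The Igf2 level was lowest on the arrays with the lowest fibroblast markers. No probe carried the name H19 here, so the H19 level was not analysed here. The groups are therefore called the Igf2-labelled and H19-labelled arrays.

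**Figure D1:**
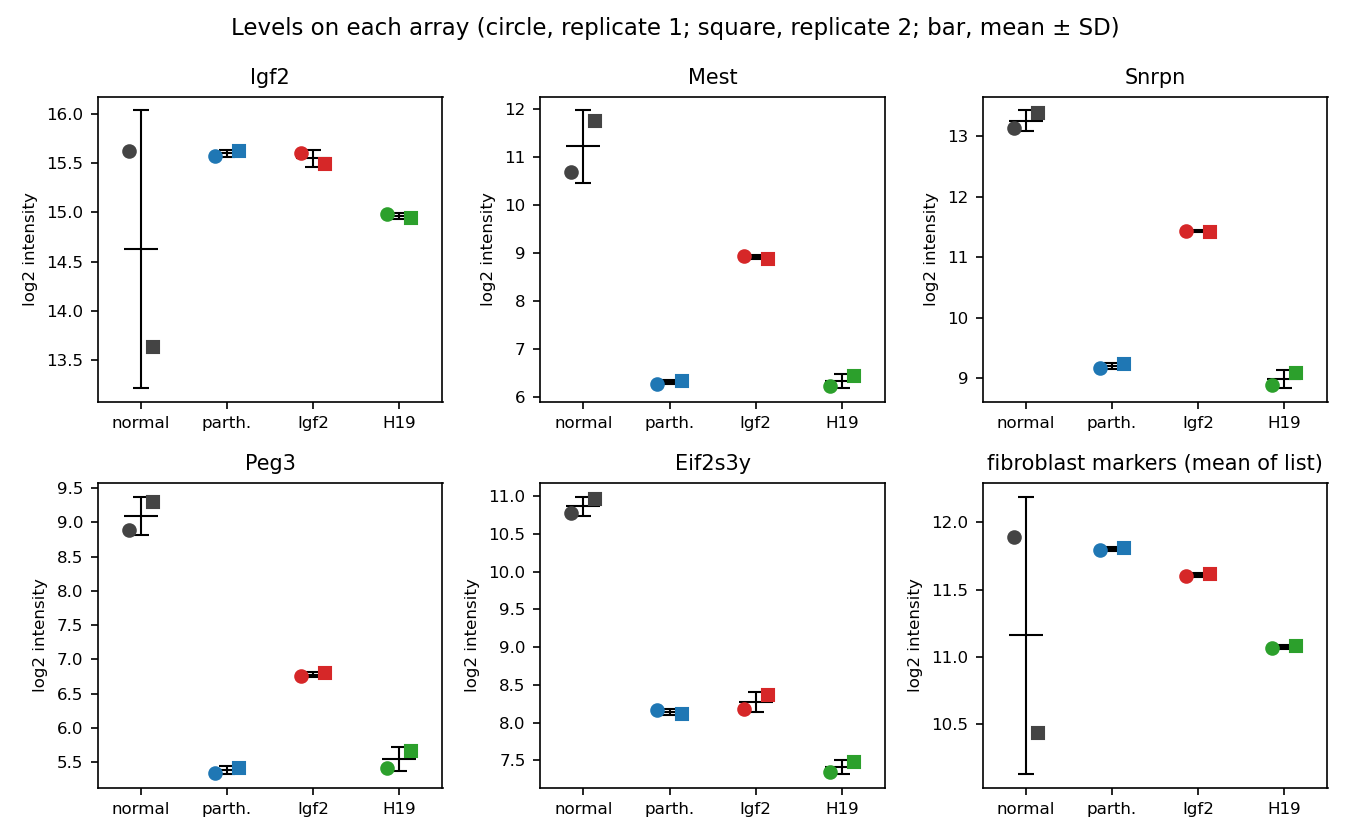
Log2 intensity (vertical axes) of Igf2, Mest, Snrpn, Peg3 and Eif2s3y and the mean of the fibroblast markers on each array, by group (horizontal axes); circles are replicate 1, squares replicate 2, and bars the mean ± SD of 2 arrays. Snrpn stood at 13.26 in normal and 9.20 in parthenogenetic ES cells, at 11.43 on the Igf2-labelled and at 8.99 on the H19-labelled arrays, while Igf2 averaged 15.60 in parthenogenetic ES cells and 15.55 on the Igf2-labelled arrays.

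The comparison of parthenogenetic with normal ES cells asks what the lack of a paternal genome changes. Falls included those of paternally expressed imprinted genes. Mest, a gene of the hydrolase family, was at least 25.9-fold lower in parthenogenetic ES cells (adjusted p = 0.00322), where its probe was not detected. Snrpn, a splicing factor gene of the Prader-Willi region, fell by 4.06 on the log2 scale (adjusted p = 1.81e-04), from 13.26 ± 0.17 to 9.20 ± 0.06 (SD, 2 arrays each). Peg3, a zinc finger gene, was at least 5.91-fold lower (adjusted p = 6.49e-04). The Y-linked gene Eif2s3y fell by 2.73 (adjusted p = 6.49e-04). The cadherin family gene Cdhr1 rose by 1.18 (adjusted p = 0.0386), and Mup2, of the major urinary protein family, passed (adjusted p = 0.0378) without being detected in either group.

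Of the 14 measured paternally expressed genes, 3 fell over all genes tested and 6 adjusted over the list alone, which added Impact and Ddc at -0.79 and -0.92 and Peg10, not detected in parthenogenetic ES cells (list adjusted p = 3.25e-04; adjusted p = 0.126 with an estimated correlation). Of the 24 maternally expressed genes, 20 were higher, 0 passed over all genes and 1, the growth factor adaptor gene Grb10 at 0.60, passed adjusted over the list alone (list adjusted p = 9.89e-04; adjusted p = 0.126 with an estimated correlation). Fibroblast markers were higher for 29 of 30 genes with a median of 0.67 (adjusted p = 1.55e-05; adjusted p = 0.529 with an estimated correlation). Hypoxia and glycolysis genes were higher beside them for 25 of 26 with a median of 0.66 (adjusted p = 1.08e-08; adjusted p = 0.454 with an estimated correlation). Germ cell genes were lower for 10 of 12 with a median of -0.63 (adjusted p = 3.25e-04; adjusted p = 0.454 with an estimated correlation). None of these last 3 lists had a member past the threshold over all genes. Without normal replicate 2 the fibroblast median was -0.07 (adjusted p = 0.0847), the hypoxia median 0.19 (adjusted p = 0.00152) and the germ cell median -0.17 (adjusted p = 0.0898), and without normal replicate 1 the fibroblast and hypoxia medians were 1.40 and 1.07 and the adjusted p of the paternally expressed list was 0.209.

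In total 3 probes were higher and 11 lower, and 1420 had an unadjusted p under 0.05 in limma. Snrpn, Peg3 and Eif2s3y stayed past the threshold whichever array was left out, and Mest did without 6 of the 8, missing it without either parthenogenetic array (adjusted p at most 0.0873). The count of 14 was 5193 without normal replicate 1, 113 without normal replicate 2, 3 without either parthenogenetic array and 9 without any of the 4 other arrays. In the limma fit of these 2 groups alone 0 probes passed, all 6 named calls among the losses, and 519 had an unadjusted p under 0.05. In simulations of unchanged groups with each probe's own spread in the normal group, 176 passed on average.

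The comparison of the Igf2-labelled arrays with parthenogenetic ES cells asks how the line labelled Igf2 differed from them. It cannot separate the modification from other differences between the lines, such as the chromosome 6 level and fibroblast markers described here. The paternally expressed genes Mest, Snrpn and Peg3 rose without reaching the level of normal ES cells. Mest was at least 5.24-fold higher (adjusted p = 0.0274), Snrpn rose by 2.23 (SE 0.13, adjusted p = 0.00204) and Peg3 was at least 1.19-fold higher (adjusted p = 0.0258). Against normal ES cells, Mest fell by 2.31, Snrpn fell by 1.83 and Peg3 fell by 2.31 (adjusted p = 0.0304, 0.00344 and 0.00344). Eif2s3y was 8.27 on the Igf2-labelled arrays and 8.14 in parthenogenetic ES cells (adjusted p = 0.845). Of the 14 paternally expressed genes, 3 rose over all genes, 7 rose and 1 fell adjusted over the list alone, and 5 were lower (adjusted p = 9.36e-05; adjusted p = 0.0998 with an estimated correlation). The other probes of Mest, at 1.76 and 1.15, and of Snrpn, at 1.35, were higher but did not pass.

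Genes of the primed epiblast were lower together on the Igf2-labelled arrays. All 12 measured members were lower with a median of -0.58, and 3 fell over all genes and 7 adjusted over the list alone (adjusted p = 1.33e-08; adjusted p = 0.0791 with an estimated correlation). Wnt8a, a WNT ligand gene, was at least 2.00-fold lower (adjusted p = 0.00275), and the transcription factor genes Pou3f1 and Lef1 changed by -1.31 and -1.08 (adjusted p = 0.0193 and 0.0341). Of the 10 mesoderm and primitive streak genes 3 fell, the WNT target Sp5 at -2.43, the homeobox gene Cdx1 at -1.02 and Fgf17 at -0.83 (list adjusted p = 0.00348; adjusted p = 0.252 with an estimated correlation). The NODAL antagonist genes Lefty2 and Lefty1 changed by -1.65 and -1.36, and the WNT inhibitor gene Notum fell by 1.47. Rasgrp1 was at least 3.13-fold lower, and Nsg2, Tnfrsf19, Olig1, Map2 and Krt8 changed by -1.84, -1.74, -1.68, -1.13 and -0.80, all past the threshold.

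Rises beyond the imprinted genes included Mup2, at least 6.12-fold higher (adjusted p = 5.32e-04), and the X-linked homeobox genes Rhox9 and Rhox6, up 2.70 and 2.68 (adjusted p = 0.00163 and 8.76e-04). Tex13b rose by 1.66, Gpr19 by 1.29 and Dppa3, a gene of germ cells and naive pluripotency, by 0.86. Of the 12 germ cell genes 11 were higher with a median of 0.46, 0 past the threshold over all genes and 3 adjusted over the list alone (adjusted p = 8.69e-04; adjusted p = 0.528 with an estimated correlation). Cholesterol synthesis genes were lower for 16 of 18 with a median of -0.23 and 0 past the threshold (adjusted p = 8.51e-04; adjusted p = 0.103 with an estimated correlation). Fibroblast markers were lower beside these groups for 27 of 30 genes with a median of -0.23 (adjusted p = 0.202, or 3.57e-05 without both normal arrays; adjusted p = 0.83 with an estimated correlation over all arrays).

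In all, 35 probes were higher and 35 lower on the Igf2-labelled arrays, 46 of them by at least 2-fold. The count of 70 was 1254 without either normal array or without both, a fit chosen after the data were seen, and the 70 were among them. It was 4 without either parthenogenetic array, 2 and 3 without Igf2-labelled replicates 1 and 2, and 11 without either H19-labelled array. Mup2 and Rhox6 stayed past the threshold whichever array was left out. Without a parthenogenetic or an Igf2-labelled array Snrpn missed it at changes of 2.19 to 2.27 (adjusted p at most 0.0733), and Mest and Peg3 passed only without a normal array (adjusted p otherwise at most 0.315 and 0.320).

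The comparison of the H19-labelled arrays with parthenogenetic ES cells asks how the line labelled H19 differed from them. Here too the modification cannot be separated from other differences between the lines. Fibroblast markers were lower in this comparison, as given below, and germ cell genes were higher together. All 12 measured were higher with a median of 1.14, and 5 rose over all genes and 9 adjusted over the list alone (adjusted p = 5.33e-07; adjusted p = 0.368 with an estimated correlation). Dazl, an RNA-binding regulator of germ cells, rose by 2.14 (SE 0.29, adjusted p = 0.0172), Asz1 by 1.64 (adjusted p = 0.013), the meiotic cohesin gene Smc1b by 1.23 (adjusted p = 0.00667) and Taf7l by 1.22 (adjusted p = 0.0198). Other rises were Xlr4a by 2.46, Tex13b by 2.04, the water channel gene Aqp3 by 1.95, the oocyte gene Khdc3 by 1.84, and Rhox6 and Rhox9 by 1.83 and 1.52. Klk1, Il4i1 and Myl7 were at least 3.70-, 3.02- and 3.01-fold higher.

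Several falls on the H19-labelled arrays were also seen on the Igf2-labelled arrays. Sp5 fell by 3.16 (SE 0.25, adjusted p = 0.0036), Pou3f1, Lefty1 and Tnfrsf19 changed by -1.64, -1.60 and -1.75, and Wnt8a, Rasgrp1 and Nsg2 were at least 1.94-, 3.05- and 3.53-fold lower. The keratin genes Krt8 and Krt18 changed by -1.82 and -1.34, the transcription factor gene Wt1 fell by 2.57, and Fst, an activin antagonist gene, fell by 1.79. The Y-linked gene Eif2s3y also passed, and changed by -0.79 to -0.66 over the fits without 1 array. Of the 12 primed epiblast genes 2 fell and 1, Otx2, rose by 0.82 (list adjusted p = 0.00262; adjusted p = 0.368 with an estimated correlation). Of the 24 maternally expressed imprinted genes 3 fell over all genes and 4 adjusted over the list alone, among them the growth inhibitor gene Cdkn1c at -1.56, Atp10a at -0.99 and the IGF2 receptor gene Igf2r at -0.59 (list adjusted p = 0.0273; adjusted p = 0.368 with an estimated correlation). Mest was detected in neither of these 2 groups, Snrpn differed by -0.22 without passing (adjusted p = 0.365), and the paternally expressed genes that passed were Ddc at 1.07, Slc38a4 at 0.94 and Inpp5f at -0.71.

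Fibroblast markers were lower on the H19-labelled arrays for 28 of 30 genes with a median of -0.81, and Ccn2 fell by 0.81 as the 1 member past the threshold (list adjusted p = 2.64e-05; adjusted p = 0.528 with an estimated correlation). Actin and matrix adhesion genes were lower for 23 of 24 with a median of -0.80, of which Krt8, Krt18 and Lamb1 fell (list adjusted p = 8.97e-07; adjusted p = 0.479 with an estimated correlation). Interferon response genes were lower for 27 of 30 with a median of -0.58, of which Mx2 fell (list adjusted p = 7.86e-06; adjusted p = 0.502 with an estimated correlation). Neural ectoderm genes had a median of -0.74, and Map2, Sox21 and Gap43 fell while the axonal gene Mapt rose by 1.77 (list adjusted p = 4.82e-04; adjusted p = 0.368 with an estimated correlation). Of the 31 pluripotency genes Jam2 rose by 0.85 and Lefty1 and Klf2 fell, with a median of 0.20 (list adjusted p = 0.0346; adjusted p = 0.455 with an estimated correlation). Without H19-labelled replicate 1 the pluripotency list's adjusted p was 0.0513, and without parthenogenetic replicate 2 its median was 0.13.

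Further lists differed in the same comparison. Insulin and IGF signalling genes were lower for 19 of 21 with a median of -0.48 (adjusted p = 0.00751; adjusted p = 0.455 with an estimated correlation), and Igf2r fell while Igf2bp3 rose by 0.94. Mesoderm and primitive streak genes were lower for 8 of 10 (adjusted p = 0.0273; adjusted p = 0.368 with an estimated correlation), and Sp5 and Fgf17 fell. Cell cycle genes were higher for 24 of 30 with a median of 0.27 (adjusted p = 0.0141; adjusted p = 0.528 with an estimated correlation), and E2f1 rose by 0.59. The p53 target list had a median of -0.34 (adjusted p = 0.0346; adjusted p = 0.566 with an estimated correlation), with an adjusted p of 0.116 without parthenogenetic replicate 1. The imprinted gene network described with H19 had a median of -0.53 (adjusted p = 0.0442; adjusted p = 0.368 with an estimated correlation), with adjusted p of 0.0905, 0.0631 and 0.0877 without parthenogenetic replicate 1, parthenogenetic replicate 2 and H19-labelled replicate 1. The 9 lists that did not pass included the trophectoderm, endoderm, DNA methylation, heat shock, and X-inactivation and Y-linked genes, with medians of 0.14, -0.08, 0.16, 0.06 and -0.40 (adjusted p = 0.656, 0.19, 0.182, 0.857 and 0.166). The other 4 were the paternally expressed, hypoxia and glycolysis, cholesterol synthesis, and ER and amino acid stress genes, with medians of -0.10, -0.02, 0.07 and 0.06 (adjusted p = 0.754, 0.441, 0.513 and 0.267).

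In all, 326 probes were higher and 237 lower on the H19-labelled arrays, 196 of them by at least 2-fold. The count of 563 was 4288 without either normal array or without both, 101 without either Igf2-labelled array, 13 without parthenogenetic replicate 1, and 0 without parthenogenetic replicate 2 or either H19-labelled array, where 2978 probes had an unadjusted p under 0.05 in limma over all arrays. Of the 51 named genes past the threshold, 0 kept it without parthenogenetic replicate 2 or either H19-labelled array, 9 without parthenogenetic replicate 1 and 23 without either Igf2-labelled array. Over these, Dazl changed by 2.10 to 2.18 (adjusted p at most 0.162) and Sp5 by -3.31 to -3.01 (adjusted p at most 0.0731).

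**Figure D2:**
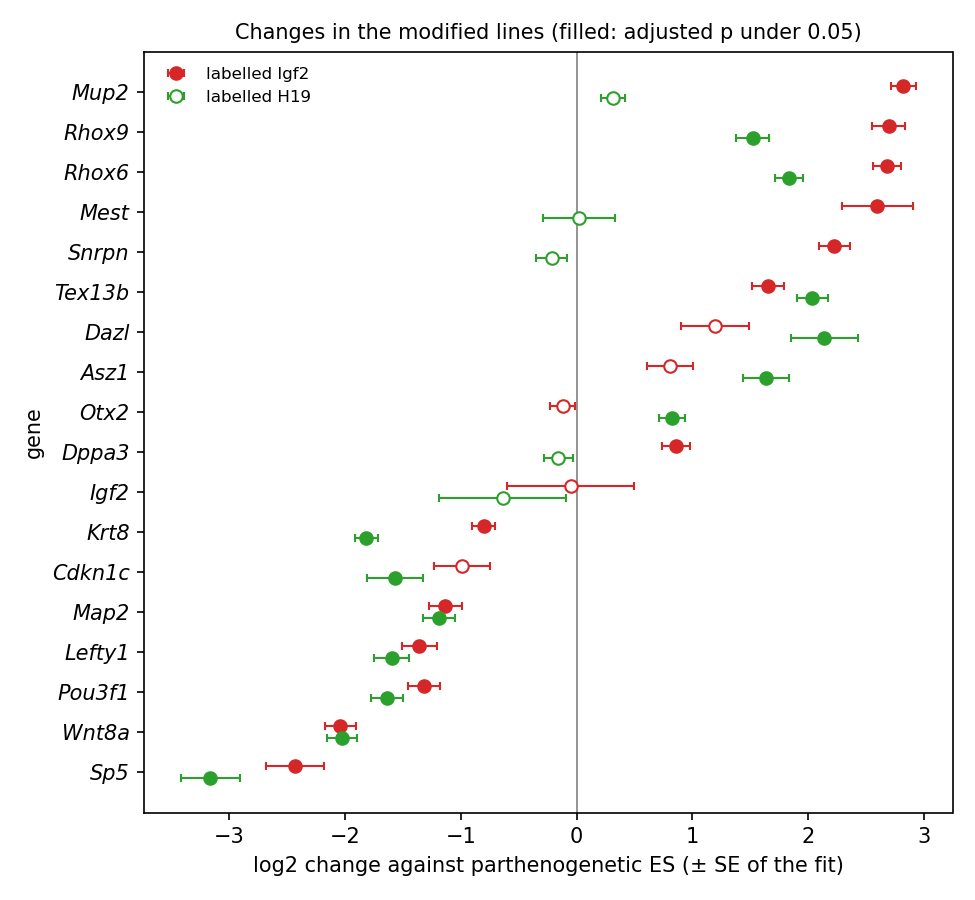
Log2 change against parthenogenetic ES cells (horizontal axis, ± SE of the fit) of 18 named genes (vertical axis) on the Igf2-labelled (red) and H19-labelled (green) arrays, 2 arrays a group; filled circles passed an adjusted p of 0.05. Sp5 changed by -2.43 and -3.16, while Snrpn changed by 2.23 on the Igf2-labelled and by -0.22 on the H19-labelled arrays.

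Genes of chromosome 6 were higher in both modified lines. Among its 443 genes the median change against parthenogenetic ES cells was 0.32 on the Igf2-labelled arrays (adjusted p = 1.43e-33; adjusted p = 5.09e-04 with an estimated correlation) and 0.41 on the H19-labelled arrays (adjusted p = 2.46e-17; adjusted p = 0.00193 with an estimated correlation). Of these genes 84.7% and 76.5% were higher, against 39.2% to 48.3% and 42.6% to 59.1% on each other chromosome. Against normal ES cells the medians were 0.34 and 0.36 (adjusted p = 1.35e-24 and 3.33e-20; adjusted p = 9.55e-04 and 0.00142 with an estimated correlation), while parthenogenetic and normal ES cells differed by -0.02 there. Chromosome 6 held 72 of the 205 genes called higher on the H19-labelled arrays, or 35.1%, against 5.07% of the genes tested (Fisher's exact test, two-sided, adjusted p = 1.31e-41 over 8 such tests). It held 8 of the 22 on the Igf2-labelled arrays (adjusted p = 1.87e-05). Named rises on chromosome 6 were Mest, Gpr19 and Dppa3 in the Igf2-labelled comparison. In the H19-labelled comparison they were Asz1, Igf2bp3, Pdia4 (0.91), Slc2a3 (0.74) and Hk2 (0.64). Chromosome 6 genes were not set aside in the tests of gene lists, so this shift can enter lists that hold them. Chromosome X genes were lower in parthenogenetic than in normal ES cells by a median of -0.09 (adjusted p = 0.0445; adjusted p = 0.967 with an estimated correlation), with an adjusted p of 0.976 without normal replicate 1, 0.133 without parthenogenetic replicate 2 and 0.0546 without either H19-labelled array, and a median of -0.14 without normal replicate 2. On the H19-labelled arrays they were lower than in normal ES cells by a median of -0.14 (adjusted p = 0.00638; adjusted p = 0.384 with an estimated correlation), which was -0.0452 without normal replicate 1 (adjusted p = 0.937).

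**Figure D3:**
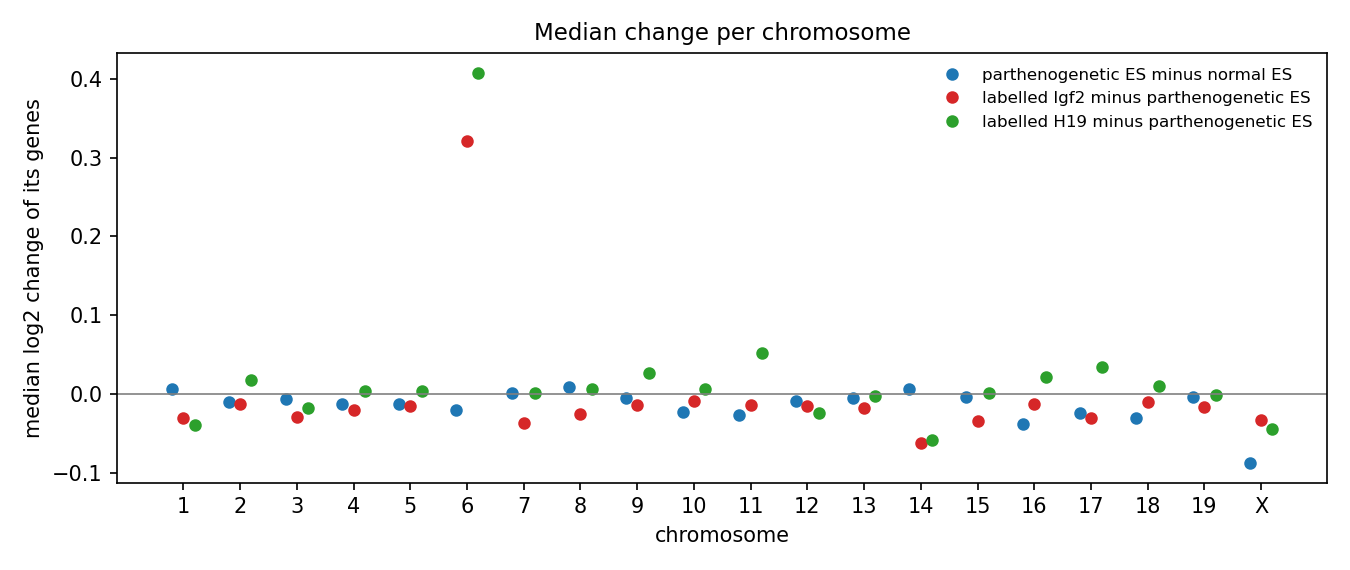
Median log2 change (vertical axis) of the genes of each chromosome (horizontal axis) in 3 comparisons, with 2 arrays a group. The chromosome 6 medians were 0.32 on the Igf2-labelled and 0.41 on the H19-labelled arrays against parthenogenetic ES cells, and every other median lay between -0.09 and 0.05.

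Both modified lines were set against the same parthenogenetic arrays, which adds likeness between the comparisons. They shared 24 probes called higher and 27 called lower, against 0.882 and 0.641 for independent lists (Fisher's exact test, one-sided, adjusted p = 1.21e-30 and 1.55e-40 over 8 tests). That test assumes independent lists, which the shared arrays rule out, so its p-values do not measure a common response to the modifications. Chromosome 6 genes, higher in both lines, were not set aside. Across probes, which are not independent replicates, the changes correlated at 0.607 against 0.502 simulated without changes, with a covariance of 0.0712 against 0.00688. The shared count of 51 was 951 without either normal array, 0 without parthenogenetic replicate 2 or either H19-labelled array, 1 without parthenogenetic replicate 1 or Igf2-labelled replicate 1, and 2 without Igf2-labelled replicate 2.

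The modified lines were also compared with normal ES cells, which asks how far each stood from cells with both parental genomes. On the Igf2-labelled arrays Eif2s3y fell by 2.59 (adjusted p = 0.00137), and Pramel37, Lefty2, Sp5, Fgf17, Map2 and Pou3f1 changed by -2.85, -2.17, -2.05, -1.15, -1.04 and -1.01. Wnt8a was at least 2.23-fold lower. Mup2 was at least 5.70-fold and Krtdap at least 2.90-fold higher, and Rhox9 and Rhox6 rose by 1.78 and 1.76. The chaperone genes Pdia4 and Pdia6 rose by 0.92 and 0.82, within an ER and amino acid stress list that was higher for 23 of 27 genes (adjusted p = 3.03e-05; adjusted p = 0.184 with an estimated correlation). Beside it fibroblast markers were higher for 28 of 30, hypoxia and glycolysis genes for 24 of 26, interferon response genes for 26 of 30 and actin and matrix adhesion genes for 21 of 24 (adjusted p = 0.0121, 2.00e-04, 0.0339 and 0.0339; adjusted p = 0.834 for each with an estimated correlation). Their medians of 0.52, 0.40, 0.27 and 0.45 were 1.18, 0.86, 0.50 and 0.97 without normal replicate 1, and -0.32, -0.0179, -0.16 and -0.0639 without normal replicate 2. The interferon list missed the threshold without Igf2-labelled replicate 1 (adjusted p = 0.0888) and the actin list without either Igf2-labelled array (adjusted p = 0.0633 and 0.0619). In simulations of unchanged groups, 174 probes passed on average with each probe's own spread in the normal group, and 0.59 with that spread moderated. The 136 probes observed comprised 58 higher and 78 lower. The count was 5300 and 906 without normal replicates 1 and 2, 20 without either parthenogenetic array, 2 without either Igf2-labelled array and 21 without either H19-labelled array. Eif2s3y and Mup2 stayed past the threshold whichever array was left out, but in the fit of these 2 groups alone 2 probes passed and 1 of 20 named calls was kept.

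On the H19-labelled arrays Mest was at least 24.6-fold and Peg3 at least 5.61-fold lower than in normal ES cells, and Snrpn, Eif2s3y, Peg10 and Impact changed by -4.27, -3.46, -1.43 and -1.02. Of the 14 paternally expressed genes 5 fell, and 7 adjusted over the list alone (adjusted p = 0.00313, or 0.184 without normal replicate 1; adjusted p = 0.237 with an estimated correlation). Sp5, Spink1, Krt8, Pou3f1 and Krt18 changed by -2.78, -2.43, -1.79, -1.33 and -1.26. Cbln1, Khdc3 and the MHC class II gene H2-Ab1 rose by 2.53, 2.23 and 2.19, Myl7 was at least 2.80-fold higher, and Asz1 and Otx2 rose by 1.36 and 1.19. Hypoxia and glycolysis genes were higher for 25 of 26 with a median of 0.66, and Pfkp, Hk2 and Slc2a3 rose by 1.48, 0.80 and 0.71 (list adjusted p = 1.38e-07; adjusted p = 0.484 with an estimated correlation), with a median of 1.09 without normal replicate 1 and 0.27 without normal replicate 2 (adjusted p = 3.04e-13 and 0.0138). Of these genes Hk2 and Slc2a3 are on chromosome 6, where the median change was 0.36 in this comparison. In simulations of unchanged groups, 173.7 probes passed on average with each probe's own spread in the normal group, and 0.4 with that spread moderated. The 650 probes observed comprised 381 higher and 269 lower. The count was 3948 and 3952 without normal replicates 1 and 2, 212 without either parthenogenetic array, 248 without either Igf2-labelled array, and 36 and 45 without H19-labelled replicates 1 and 2. Mest, Snrpn, Peg3 and Eif2s3y stayed past the threshold whichever array was left out, but in the limma fit of these 2 groups alone 0 probes passed, all 44 named calls were lost and 1518 probes had an unadjusted p under 0.05.

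The direct comparison of the modified lines tests their difference. On the H19-labelled arrays Mest was at least 4.97-fold lower than on the Igf2-labelled arrays (adjusted p = 0.044), and Mup2, Snrpn, Clca3b, Rhox9, Dppa3 and Krt8 changed by -2.51, -2.44, -1.86, -1.18, -1.01 and -1.01. Ldhc, Olig1, Zap70, Cyp2s1 and Otx2 rose by 1.23, 1.07, 1.07, 0.98 and 0.94. Germ cell genes were higher for 11 of 12 with a median of 0.65, 0 past the threshold over all genes and 7 adjusted over the list alone (adjusted p = 1.73e-05; adjusted p = 0.382 with an estimated correlation). Fibroblast markers were lower beside them for 27 of 30 with a median of -0.62 (adjusted p = 3.70e-05; adjusted p = 0.539 with an estimated correlation). In all 26 probes passed, 11 higher and 15 lower, and 1800 had an unadjusted p under 0.05 in limma. The count was 2663 without either normal array, 3 without either parthenogenetic array, 0 without either Igf2-labelled array or H19-labelled replicate 1, and 2 without H19-labelled replicate 2.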

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

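The fits without both normal arrays and with the fibroblast covariate were chosen after the data were seen. Within groups the covariate differed mainly between the normal arrays (11.89 and 10.43), so it takes up their gap and says little about fibroblast RNA. Chromosome 6 kept its call and direction in every alternative run against parthenogenetic ES cells, with medians of 0.27 to 0.35 on the Igf2-labelled and 0.35 to 0.43 on the H19-labelled arrays. Of 157 calls of named genes, 149 kept their call with no background model, 151 in the authors' table, 157 without either normal array, 113 with array weights, 104 with the replicate number as a block, 88 in fits of the groups compared alone and 28 to 60 without 1 array of another group, and none changed sign. Of 58 list calls none kept its call with an estimated correlation. Counts below run over parthenogenetic against normal, Igf2-labelled and H19-labelled against parthenogenetic, the same lines against normal, and H19-labelled against Igf2-labelled, and the reported counts were 14, 70, 563, 136, 650 and 26. Leaving out 1 array gave 3 to 5193, 2 to 1254, 0 to 4288, 2 to 5300, 36 to 3952 and 0 to 2663, and leaving out both normal arrays gave 1254, 4288 and 2663 for the comparisons without them. The lowest and highest counts without 1 array rest on equally many arrays in all, but not always on equally many in the groups compared. In comparisons without normal ES cells, the highest kept 2 arrays in both groups compared. Each lowest count left 1 array in a group compared, which may have lowered it further. The highest came without a normal array, when the gap between the normal arrays no longer entered the shared spread. The lowest came without an array of another group, when that gap weighed more in it. Fits of the groups compared alone gave 0, 874, 4039, 2, 0 and 2271. Array weights gave 9, 1354, 4649, 23, 61 and 2859, and the covariate 125, 1264, 2034, 1204, 3353 and 743. The replicate block gave 26 and 314 against parthenogenetic, 47 for Igf2-labelled against normal and 3 for the modified lines, and the trended prior 111 and 207 for the Igf2-labelled arrays against parthenogenetic and normal. Detection on all arrays gave 2 and 9 for the first and last, and 8 and 17 came from the authors' table. Both tested fewer probes. Other counts stayed within 1.5-fold. Igf2 on the H19-labelled against parthenogenetic arrays passed at -0.64 in the fit of those groups alone, with array weights and without either or both normal arrays, over -0.66 to -0.61 without 1 array.

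Probes called alike in both modified lines, 51 as reported, numbered 668 in fits of the groups compared alone, 1030 with array weights, 92 with the trended prior, 19 with the block, 78 with no background model, 801 with the covariate, 951 without both normal arrays and 0 to 951 without 1 array. Probes called in opposite directions between parthenogenetic against normal and Igf2-labelled against parthenogenetic, 4 as reported, numbered 0 with those groups alone, 1 with detection on all arrays, 7 with array weights, 2 with no background model or no filter, 53 with the covariate and 0 to 518 without 1 array. For the H19-labelled line the 2 reported became 0 with detection on all arrays, the authors' table, those groups alone, array weights, the block, no background model, no filter or an offset of 50, 1 with the trended prior, 49 with the covariate and 0 to 2283 without 1 array. Lists past the threshold, 12, 5, 13, 6, 9 and 13 as reported, numbered 0 in each with an estimated correlation. For Igf2-labelled against parthenogenetic they were 8 with no background model or in the authors' table, 9 with the block, 10 without both normal arrays and 5 to 10 without 1 array. They were 8 for H19-labelled against parthenogenetic with the covariate, and without 1 array 7 to 12 for parthenogenetic and 4 to 11 for Igf2-labelled against normal. Chromosomes past the threshold for parthenogenetic against normal, 1 as reported, were 0 with an estimated correlation, the block or the mean over a gene's probes, and 0 to 1 without 1 array. For Igf2-labelled against normal, 1 as reported, they were 2 with the covariate and 1 to 2 without 1 array, and for H19-labelled against normal, 2 as reported, 1 with an estimated correlation and 1 to 2 without 1 array.

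Results that changed direction, none of them a gene call as reported, did so mostly with a normal array left out, and the cause was not tested. In parthenogenetic against normal, the range without 1 array was -0.29 to 0.44 for Dnmt3b and -0.69 to 0.79 for Rhox5. In Igf2-labelled against normal it was -1.01 to 0.75 for Phlda2, which was 0.41 with the covariate. In H19-labelled against normal it was -1.03 to 0.85 for Acta2, -0.44 to 1.13 for Anxa2, -0.67 to 0.55 for Bgn, -0.66 to 1.33 for Igf2, -0.92 to 0.98 for Igfbp7, -0.81 to 0.95 for Phlda2, -0.65 to 0.34 for S100a11, -0.61 to 0.53 for Snai1, -0.60 to 0.29 for Tex19.1 and -0.75 to 0.41 for Vim. With the covariate Anxa2 was 0.42 and Zscan4c -0.80 in H19-labelled against parthenogenetic, and Phlda2 was -0.44 in H19-labelled against Igf2-labelled. List medians without 1 array in parthenogenetic against normal were -0.0651 to 1.40 for fibroblast markers, -0.12 to 0.55 for p53 targets, -0.0615 to 0.65 for interferon response and 0.00676 to 0.97 for actin and matrix adhesion, whose test turned though its median did not. In Igf2-labelled against normal they were -0.32 to 1.18 for fibroblast markers, -0.16 to 0.50 for interferon response, -0.0179 to 0.86 for hypoxia and glycolysis and -0.0639 to 0.97 for actin and matrix adhesion. In H19-labelled against normal they were -0.57 to 0.11 for interferon response and -0.80 to 0.35 for actin and matrix adhesion. With the covariate p53 targets were -0.0769 in parthenogenetic against normal and -0.0761 in H19-labelled against parthenogenetic, where the test's direction turned though the median did not. Interferon response was then -0.0194 in parthenogenetic against normal and 0.0327 in Igf2-labelled against normal, again with the test's direction turned in the latter. Signal near background limits the folds given as at least, since a probe not detected in a group has only an upper bound there.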

Other observations

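Of the tests below, those of the share of chromosome 6 genes, of the chromosome 6 median between the normal arrays and of the parts of chromosome 6 were set before their results were seen, and all others after.

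Normal replicate 2 also differed from normal replicate 1 in genes outside the fibroblast lists, and the genes named here were picked for the size of the gap. Amn, a visceral endoderm gene, stood at 10.72 on replicate 2 and 7.30 on replicate 1, Srgn at 9.35 and 6.62, the laminin gene Lama1 at 11.60 and 9.40, and Stra8, a gene of meiotic entry, at 9.50 and 7.38. In the other direction Thbs1 stood at 7.41 and 10.44, and the collagen gene Col1a2 at 9.45 and 12.25. Of 12 germ cell genes, 10 were higher on replicate 2 with a median gap of 0.83, and of 26 hypoxia and glycolysis genes 25 were lower with a median gap of -0.77. Zscan4c, a gene of the 2-cell-like state, averaged 10.52 in normal and 7.42 on the Igf2-labelled arrays (adjusted p = 0.0610). The gap between the normal arrays correlated across genes at 0.499 with the change on the H19-labelled arrays, which shares no array with it, and at 0.488 without the fibroblast and matrix lists. Of the 370 genes called on the H19-labelled arrays, 245 had the sign of that gap.

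The first pattern is the higher level of chromosome 6 genes in both modified lines. A few strongly changed genes would leave most others in place, yet 76.5% of the genes were higher in the line with fewer. Background correction and normalization did not remove it, since the lowest median was 0.27 with no background model or in the authors' table, and neither did fibroblast RNA, since the chromosome 6 median differed by 0.0468 between the normal arrays, which differ most in fibroblast markers. An extra copy of chromosome 6 in many cells of both lines is a candidate explanation: each of its 3 parts by gene order was higher in both lines, with a lowest median of 0.26. No DNA measurement was analysed here, and so whether there was such a gain stays open.

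The second pattern is the intermediate level of Mest, Snrpn and Peg3 on the Igf2-labelled arrays. On the linear scale Snrpn and Impact averaged 23.5% and 40.6% of the way from parthenogenetic to normal ES cells. Impact did not pass the threshold over all genes in that comparison and averaged -20.7% on the H19-labelled arrays, so its share is less certain. RNA of these Y-bearing normal cells cannot account for the Snrpn share in full, nor for the Impact share as measured. The whole Eif2s3y signal, part of which parthenogenetic ES cells also showed, was at most 16.9% of normal on either array. The Eif2s3y signal was lower on the H19-labelled arrays than in parthenogenetic ES cells, past the threshold in the fit of all arrays. Both groups carry only maternal genomes by their labels. A share counted from the parthenogenetic level of this gene is therefore less certain. For Mest and Peg3, at 15.5% and 3.43% or more from levels not detected, the upper bound of 16.9% leaves the cause open. As a share of the way, like the other genes, Eif2s3y stood at 0.52% and 3.02% on the Igf2-labelled arrays. It averaged -7.02% on the H19-labelled arrays. The Mest bound lay above these values and the Peg3 bound close to the highest. Fibroblast RNA would need more fibroblast marker signal than in parthenogenetic ES cells, but the mean differed by -0.19, and the chromosome 6 shift cannot account for Snrpn, which is on chromosome 7 and rose by 2.23. Partial expression from maternal alleles, a subset of cells with altered imprints, or cells without a Y chromosome from elsewhere may each remain, and none was tested.

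The third pattern is the gap between the normal arrays. A parthenogenetic array labelled normal would lack the paternally expressed genes, but Mest, Snrpn and Peg3 lay at least 2.36 above the highest parthenogenetic array on both, with probes not detected there at the lowest detected value. For the fibroblast markers, 96.7% of 30 lower on replicate 2, less fibroblast RNA cannot be told apart from lower expression in the ES cells, which would give the same. For the endoderm genes, 17 of 24 higher on replicate 2, the test did not separate less fibroblast RNA from higher expression in the ES cells. Their median exceeded that of the pluripotency genes by 0.22, short of the margin set for the test though above the highest of the other pairs, 0.0177. Their mean exceeded that of the pluripotency genes by 0.56, against -0.0118 to 0.0083 in the other pairs. The SD was 1.19 among single endoderm genes, which is not the error of their mean. The gap rests on 1 array on each side, so no conclusion is drawn. A different state of the culture stays open and was not tested.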
